A study of Mus musculus with 9 samples.

How the data were processed

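Gene expression was measured in 9 mouse lymphomas with 1 Affymetrix mouse genome array per tumour, 4 from Eμ-Myc and 5 from Eμ-Myc and Eμ-TTP-1 mice, on a strain background of 94% C57BL/6. Per the labels' protocols, RNA was prepared with a column kit and biotin-labelled cRNA was made with an in vitro transcription labelling kit. The authors deposited 1 table of probe set values that the submitters' processing notes trace to GCRMA, which corrects the background by probe sequence, normalises quantiles between arrays and summarises each probe set; the GCRMA version is not given in the sources used here. The values are on a linear intensity scale: the authors deposited intensity values from 1.56 to 123104.7 with a median near 13, which the values themselves show not to be log2. The plan had expected log2 values and allowed for linear ones; log2 was taken without a pseudocount. Scanner files and detection calls were not analysed here, so array quality, scan dates and batches could not be examined.

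Of 45037 probe sets, 34945 had 1 gene in the platform annotation, 932 had several and 9160 had none listed; those with several or none were left out of gene tests. Of the former, 34741 matched a gene of the reference table (assembly GRCm38.p6), used for names, chromosomes and the order of genes only. Each of the 18193 genes was represented by its probe set with the highest mean, and 10172 genes with a log2 value over 4, an intensity of 16, in at least 4 of the 9 arrays were tested; 458 of these probe sets have names ending in _x_at. GCRMA leaves weak probe sets with low values that still vary in log2, so folds of genes under this level are poorly determined.

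The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), without covariates. The method was tested on simulated data: of 9972 unchanged genes, 6 were called. Differences are double-transgenic minus Eμ-Myc. Lists of 537 members in 30 groups were fixed, with the named genes' rule, before the data were examined; 496 members were named on the array and 406 tested, and 28 lists entered the test. The list test was limma's camera with a preset correlation of 0.01, set beside camera with an estimated correlation, fry, and exact permutation over the 126 splits of 9 arrays into 4 and 5, whose smallest two-sided p is 0.00794. Named genes were Zfp36, Zfp36l1, Zfp36l2, Myc and Ccnd1, the 12 genes of each direction with the smallest p since none passed, with 0 skipped, and up to 2 members at each end of a list. From the last set, members of lists that passed camera, of lists with a gene past the threshold over the list alone, of TTP targets and of MYC-activated genes are named; that restriction was made after the values were seen. Genes with no probe set in the table are not analysed here.

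Alternatives were no filter and a log2 filter of 6, all probe sets, their mean, no _x_at probe sets, quantile normalisation, median centring, an intensity trend with a robust prior, array weights, a pseudocount of 16, the replicate numbers as a block, Xist as a covariate, and each array left out; centring by chromosome was added after seeing the data. For other splits of the samples, 100 of the 126 were drawn with a fixed seed.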

Results

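Lymphomas of Eμ-Myc mice, in which an immunoglobulin heavy chain enhancer drives the oncogene Myc in B cells, were compared with lymphomas of mice that carried a second transgene, Eμ-TTP-1, beside Eμ-Myc. TTP (tristetraprolin, gene Zfp36) binds AU-rich elements of mRNAs and promotes their decay. The title of the series asks about TTP as a suppressor of Myc-induced lymphoma, and the comparison addressed how established tumours with and without the TTP transgene differ in mRNA levels. RNA of 9 lymphomas, 4 Eμ-Myc and 5 Eμ-Myc with Eμ-TTP-1 (called double-transgenic here), was hybridised to 1 Affymetrix mouse array each. The labels call the samples biological replicates. The table held 45037 probe sets per array as GCRMA intensities, with a median intensity of 12.2 to 13.4 per array, and 47.6% to 48.8% of the probe sets exceeded an intensity of 16. The correlation of log2 values between arrays, across probe sets, ran from 0.970 to 0.981 within Eμ-Myc, from 0.964 to 0.990 within the double-transgenic group and from 0.959 to 0.987 between the groups. The number of arrays limits the precision of every value.

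Zfp36 mRNA was not higher in the lymphomas that carried the TTP transgene. Its single probe set read 10.57 ± 0.41 on the log2 scale in Eμ-Myc lymphomas (SD, n = 4) and 10.55 ± 0.38 in double-transgenic lymphomas (SD, n = 5), with 9.98 to 10.85 in the double-transgenic arrays and 10.20 to 11.01 in the others. The log2 difference, double-transgenic minus Eμ-Myc, was -0.02 (exact permutation p = 0.937, two-sided), and its 95% interval of -0.59 to 0.55 allowed a change between 0.663-fold and 1.47-fold. Whether these probes lie in the part of the mRNA that the transgene holds is not known, so the value does not check the genotype labels. Of the genes for related mRNA-binding proteins, Zfp36l1 had a log2 difference of -0.20 (95% interval -0.81 to 0.40) and Zfp36l2 one of 0.53 (95% interval -0.11 to 1.16, exact permutation p = 0.159, two-sided). Myc itself read 13.92 ± 0.26 in Eμ-Myc (SD, n = 4) and 14.02 ± 0.15 in double-transgenic lymphomas (SD, n = 5), a log2 difference of 0.10 with a 95% interval of -0.24 to 0.45. Ccnd1, which encodes cyclin D1, was split within each group: it read 8.86 in Eμ-Myc replicate 1 and 8.03 in double-transgenic replicate 2, against 12.22 to 12.83 in the other Eμ-Myc and 12.60 to 12.82 in the other double-transgenic arrays.

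**Figure D1:**
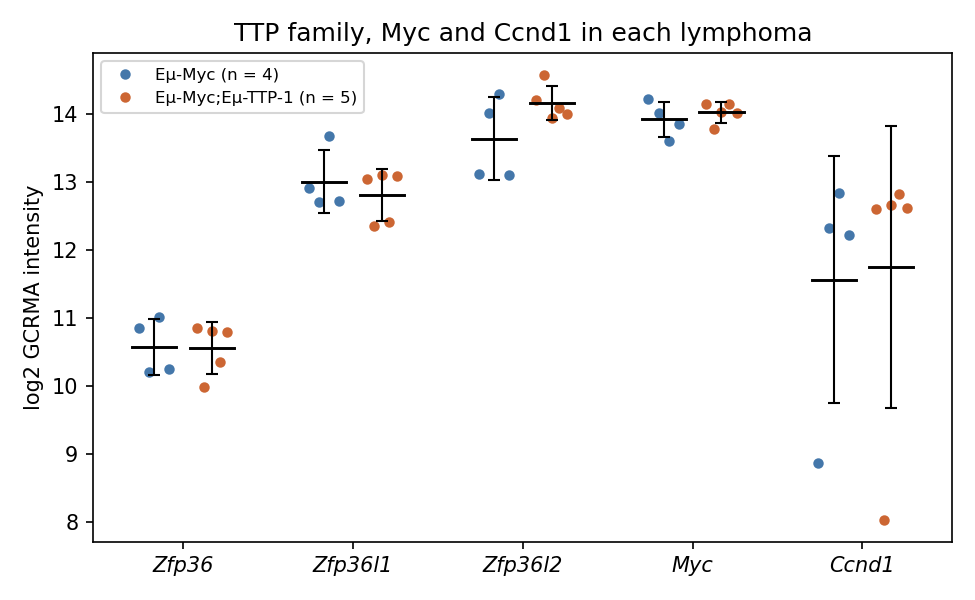
Log2 GCRMA intensity of the TTP family genes, Myc and Ccnd1 in each lymphoma. Points are arrays, horizontal bars the group means and error bars 1 SD; the groups overlap for each gene, and Ccnd1 is low in 1 array of each group.

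No gene passed the test between the genotypes. Of 10172 genes tested with limma, 0 had a Benjamini-Hochberg adjusted p under 0.05 and the lowest adjusted p from limma was 0.769. At an unadjusted p under 0.05 there were 577 genes, 5.67% of those tested, where 508.6 are expected with no effect. Of these, 394 were higher and 183 lower in double-transgenic lymphomas. The values of the groups did not overlap for 167 genes, or 1.64%, and chance gives 1.59%. Simulated changes in 50 genes of each size were recovered in 38% of genes at a log2 change of 1, 72% at 2, 90% at 3 and 92% at 4. All sizes were planted in the same simulated set. Genes called there ease the adjustment for the rest, so these shares overstate the recovery where few genes change. When every gene was given the same median SD, a log2 change of 1 was recovered in 90% of genes. That share does not carry over to the arrays, even to a gene of median SD. With 1 SD for all genes limma can pool it over genes, while its prior in the arrays had 1.69 degrees of freedom. The changes were again planted together. Ada, with a log2 difference of 1.02 and an SE of 0.229 beside a median SE of 0.228, had a limma adjusted p of 0.845.

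The 12 genes with the smallest p among those higher in double-transgenic lymphomas had log2 differences from 0.62 to 5.44. Pkm, the glycolytic enzyme pyruvate kinase, had a log2 difference of 0.79 (SE 0.14, limma adjusted p = 0.769), from 12.89 ± 0.21 in Eμ-Myc (SD, n = 4) to 13.68 ± 0.18 (SD, n = 5). Bex3 had 1.78 (SE 0.30), and its 4 Eμ-Myc values all lay below its 5 double-transgenic values. Arntl, a core transcription factor of the circadian clock also known as Bmal1, had 2.49 (SE 0.54) with 8.69 to 9.50 in Eμ-Myc and 10.06 to 12.86 in double-transgenic arrays. Ada, which encodes adenosine deaminase, had 1.02 (SE 0.23), and Cenps, a centromere protein, had 1.13 (SE 0.24). Slc25a13, a mitochondrial aspartate and glutamate carrier, had 5.44 (SE 1.22), with background values of 1.91, 2.16 and 2.23 in 3 of the Eμ-Myc arrays, 8.24 in Eμ-Myc replicate 3, and 8.77 to 9.49 in the double-transgenic arrays. Zfp820 had 3.497 (SE 0.64) and Synj2 1.42 (SE 0.21), but the Eμ-Myc values of both lay under the background range of 16, as did those of Slc25a13 apart from replicate 3, so their folds are poorly determined. The double-transgenic mean of Synj2, 4.31, was itself near background, and its other probe sets did not pass the filter. Pgm2l1 (0.62), Zfp94 (1.54), Cds2 (0.75) and Ccdc14 (0.98) complete the 12. The 4 other Cds2 probe sets that passed the filter had 0.99, 0.29, 0.016 and 8.73e-04, so its difference depended on the probe set. In none of the 12 was the limma adjusted p under 0.769.

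The 12 genes with the smallest p among those lower in double-transgenic lymphomas had log2 differences from -2.48 to -0.60. Bmpr2, a receptor of bone morphogenetic proteins, had -1.40 (SE 0.24, limma adjusted p = 0.769), from 9.63 ± 0.45 in Eμ-Myc (SD, n = 4) to 8.23 ± 0.31 (SD, n = 5). Wfdc21 had -2.43 (SE 0.44), Slc49a4 -2.26 (SE 0.49) and Kctd14 -2.48 (SE 0.61). Wapl, which releases cohesin from chromosomes, had -1.03 (SE 0.25), and Stx7, a syntaxin of endosomes, -0.99 (SE 0.25). Tmem123 (-0.66), the metalloproteinase Adam9 (-0.68), Pcdhgc4 (-1.44) and Scgb3a1 (-1.34) also belong here, as does Rnd2 at -0.60, where the double-transgenic values lay between 3.77 and 3.99 and so at background. Scgb3a1 had a double-transgenic mean of 4.29, near background, so its fold is poorly determined. Vps52 had -0.96 (SE 0.23) on a probe set whose name ends in _x_at, a class that can hybridise to other transcripts, and 0.57 on its other probe set, so its direction depended on the probe set. In none of these 12 was the limma adjusted p under 0.769.

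**Figure D2:**
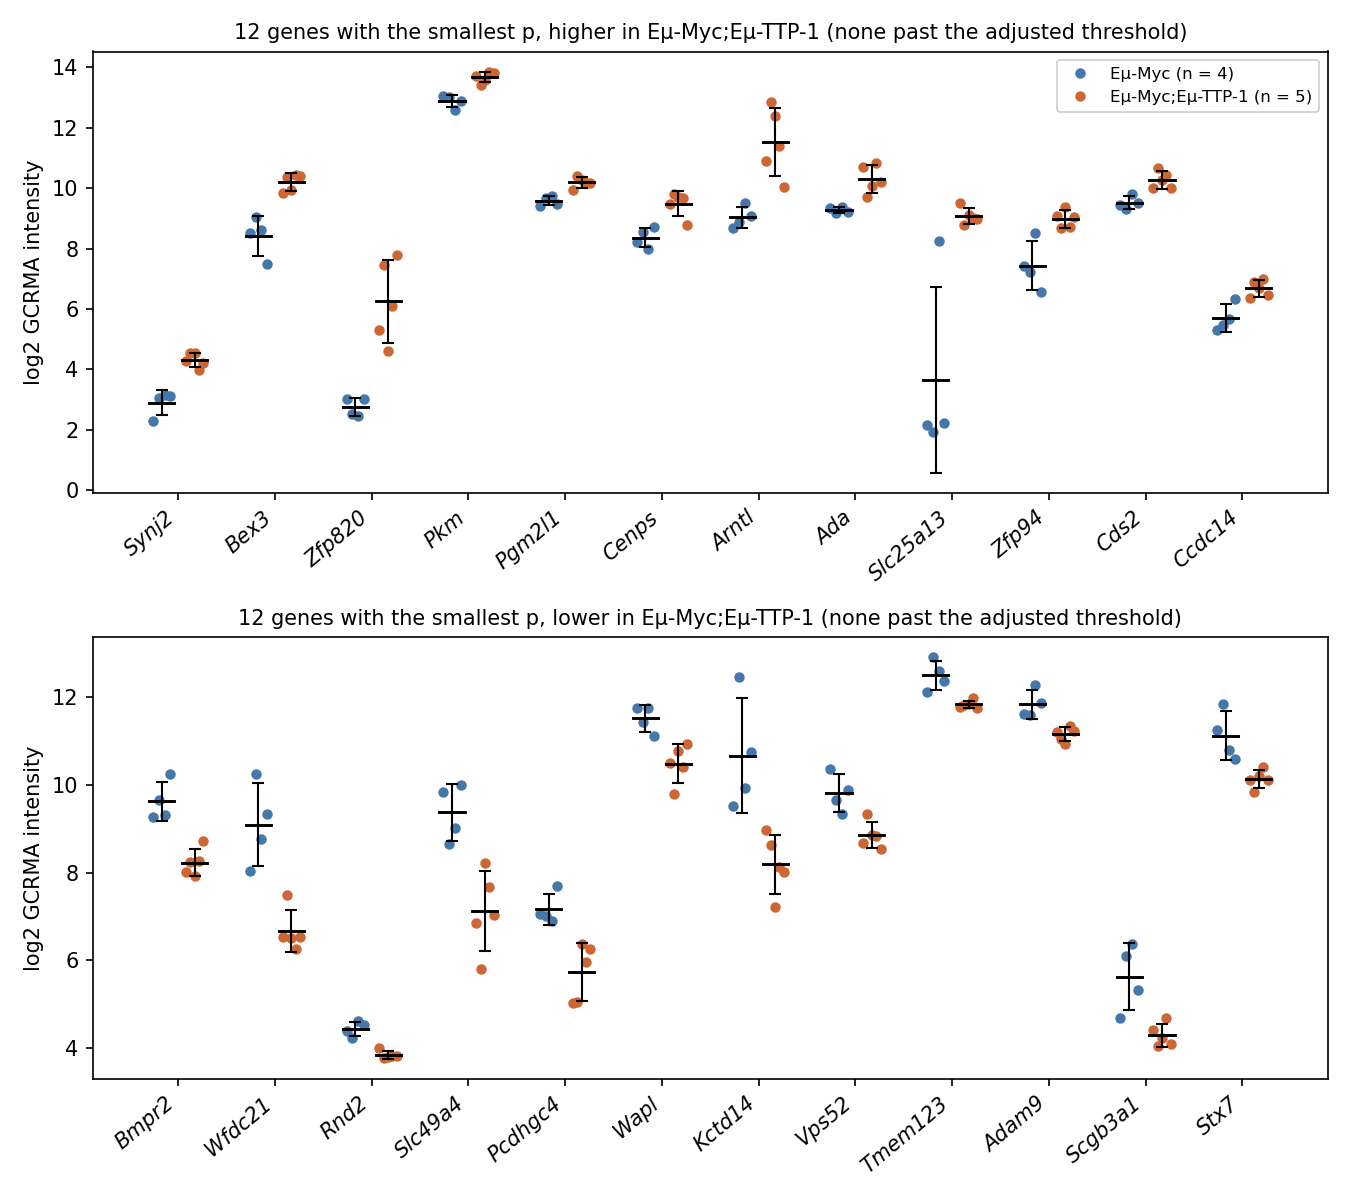
Log2 GCRMA intensity in each lymphoma of the 12 genes with the smallest p in each direction. Points are arrays, horizontal bars the group means and error bars 1 SD; Slc25a13 is at background in 3 Eμ-Myc arrays and at 8.24 in Eμ-Myc replicate 3.

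Cell cycle genes had higher mean levels in double-transgenic lymphomas. Of 23 tested S phase genes, 21 were higher in the double-transgenic group and the mean log2 difference was 0.31, and of 25 mitosis genes 24 were higher with a mean of 0.35. Gins2, of the replication helicase, had 1.07 (SE 0.33) and Prim1, a primase subunit, 0.52 (SE 0.17), while Ndc80 and Nusap1 of the mitotic spindle had 0.97 (SE 0.32) and 0.54 (SE 0.21). Ccne1, which encodes cyclin E1, went the other way with -0.68 (SE 0.41), as did Chaf1b (-0.35, SE 0.46) and, among mitosis genes, Ube2c (-0.02, SE 0.38). The sign of Chaf1b rested on Eμ-Myc replicate 1, without which its difference was 0.08. Ube2c also changed sign in some fits with 1 array left out. The mean of the mitosis list read 10.99 and 11.46 in Eμ-Myc replicates 1 and 3, 12.07 and 12.22 in the other Eμ-Myc arrays, and 11.98 to 12.12 in the 5 double-transgenic arrays. With the preset correlation of limma's camera, the S phase list had an adjusted p of 5.82e-04 and the mitosis list one of 3.73e-04. With the correlation estimated from the data, camera gave each an adjusted p of 0.899, and 0 of their genes passed when adjusted over the list alone. The exact permutation p of the list means was 0.214 for S phase and 0.278 for mitosis. Without Eμ-Myc replicate 1, the mean difference was 0.09 for S phase (camera adjusted p = 0.295) and 0.12 for mitosis (0.448), so this array carried most of the difference. Without replicate 3 the means stayed at 0.28 for S phase and 0.28 for mitosis, with camera adjusted p of 0.0533 and 0.0684.

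Markers of precursor B cells had higher and several myeloid, antigen presentation and NF-kB genes lower mean levels in the double-transgenic group. The precursor B cell list had a mean log2 difference of 1.34, with 14 of 16 tested members higher, among them the recombinase gene Rag2 (2.76, SE 1.32; 1.66 without Eμ-Myc replicate 2, where it was at background) and Vpreb3 (0.58, SE 0.23), while Dtx1 (-0.96, SE 0.46) and Cecr2 (-0.72, SE 1.499) were lower. Its mean was 6.79 in Eμ-Myc replicate 2, against 9.14 to 9.47 in the other Eμ-Myc arrays and 9.19 to 10.56 in the double-transgenic ones, and without that array the mean difference was 0.71 (camera adjusted p = 0.652). All 10 tested granulocyte genes were lower, with a mean of -1.99, among them S100a9 (-3.11, SE 1.63) and Ngp (-3.15, SE 1.68), with Ngp at background in 2 double-transgenic arrays (3.12 and 3.29). At the other end, Prtn3 was nearly unchanged (-0.02, SE 1.63) and Mmp9 had -0.99 (SE 1.28). Without Eμ-Myc replicate 3 both changed sign, to 0.51 for Prtn3 and 0.54 for Mmp9. The mean of this list ran from 4.72 to 9.89 in Eμ-Myc and from 3.85 to 9.58 in double-transgenic arrays, and without Eμ-Myc replicate 3 the mean difference was -1.21 (camera adjusted p = 0.233). The macrophage list had a mean of -0.38 with 17 of 21 genes lower, among them the scavenger receptor Marco (-2.46, SE 0.77), whose double-transgenic values of 3.11 to 4.40 lay near or under the background limit, so that its fold is poorly determined, while the lysozyme genes Lyz2 (0.46, SE 0.43) and Lyz1 (0.30, SE 0.33) were higher. The Lyz1 probe set has a name ending in _x_at, a class that can hybridise to other transcripts. The Lyz1 probe set outside that class lay at background (mean log2 2.79, difference 0.019), so the Lyz1 value may not be of a second gene. Without Eμ-Myc replicate 3 the macrophage mean was -0.175 (camera adjusted p = 0.883). Antigen presentation by class II molecules had a mean of -0.66 with 7 of 9 genes lower, among them Cd74 (-1.34, SE 0.65) and H2-Aa (-1.42, SE 0.68), both of which were lowest in double-transgenic replicates 2 and 4, while H2-Ob (0.89, SE 0.72) and H2-DMb2 (0.07, SE 0.72) were higher. Without double-transgenic replicate 2 the class II mean was -0.26 (camera adjusted p = 0.196). The NF-kB response list had a mean of -0.33 with 13 of 16 genes lower, among them Nfkbiz (-1.01, SE 0.39), while Ltb (0.285, SE 1.37) and Cflar (0.19, SE 0.26) were higher, and without Eμ-Myc replicate 1 the mean was -0.095 (camera adjusted p = 0.404). Under the preset correlation, camera's adjusted p was 0.0465 for precursor B cells, 3.73e-04 for granulocytes, 0.0486 for macrophages, 0.0179 for class II genes and 0.0141 for NF-kB. With an estimated correlation the camera adjusted p was 0.899 for each, and 0 of their genes passed when adjusted over the list alone. The exact permutation p of the list means was 0.0476 for precursor B cells, which did not pass after adjustment over the lists (0.667), 0.222 for granulocytes, 0.302 for macrophages, 0.397 for class II and 0.397 for NF-kB.

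**Figure D3:**
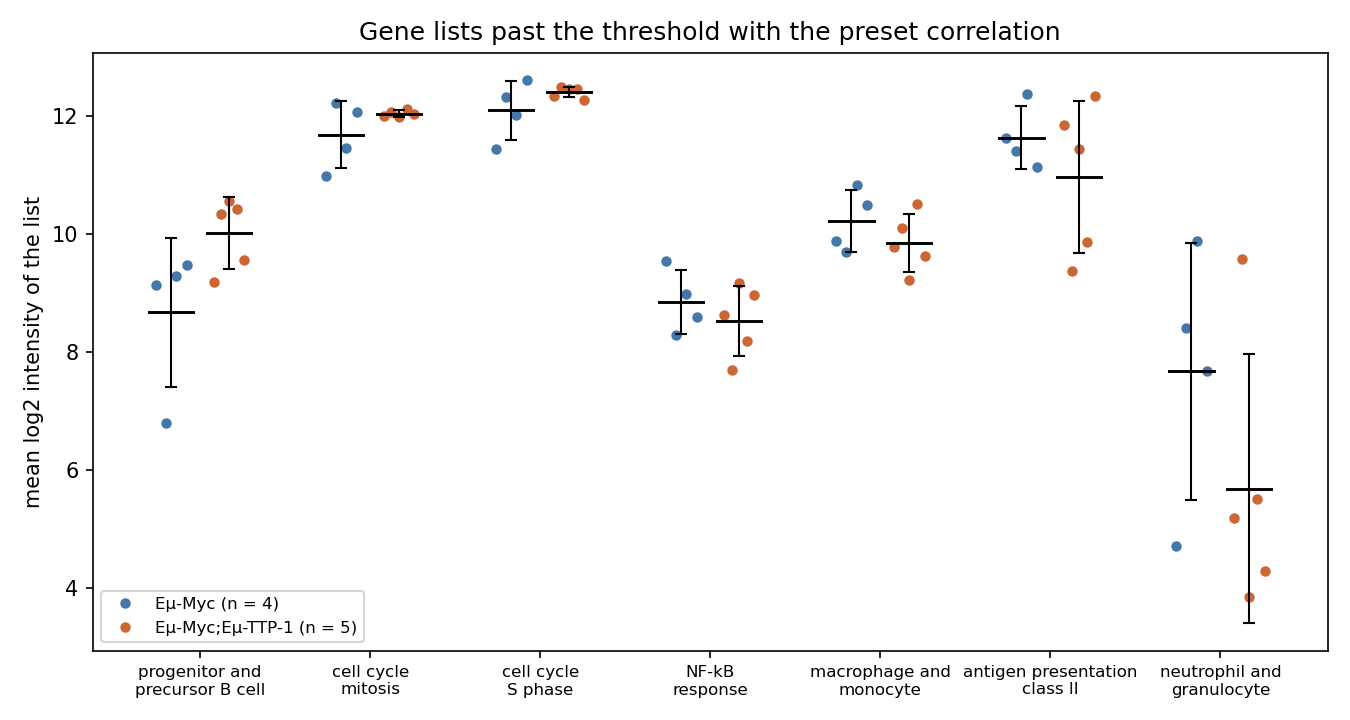
Mean log2 intensity of the 7 gene lists that passed camera with its preset correlation, in each lymphoma. Points are arrays, horizontal bars the group means and error bars 1 SD; the groups overlap for each list, and 1 Eμ-Myc array is low for precursor B cell genes.

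The tested TTP target mRNAs, 18 of the 32 in the list, were not lower as a group in lymphomas with the TTP transgene. The others were not named on the array or did not pass the filter, so nothing is known of them here. Of 18 tested targets, 12 were higher and 6 lower in double-transgenic lymphomas, the mean log2 difference was 0.22, and camera's adjusted p was 0.929. The mean ran from 0.028, without Eμ-Myc replicate 1, to 0.33 when arrays were left out in turn. Dusp1, a phosphatase of MAP kinases, had 0.76 (SE 0.27) and the growth factor gene Vegfa 1.27 (SE 0.49), while Nfkbiz had -1.01 (SE 0.39) and Birc3 -0.69 (SE 0.51). Of 33 MYC-activated nucleolar and biosynthesis genes, 15 were higher and 18 lower with a mean of 0.03, a median of -0.01 and a camera direction of lower genes (adjusted p = 0.567). Cdk4 had 0.28 (SE 0.16), Ppan 0.24 (SE 0.14) and Odc1 -0.22 (SE 0.14). Of 21 p53-activated genes 14 were higher, with a mean of 0.33 and a camera adjusted p of 0.626.

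In the erythroid list, 1 gene passed when adjusted over the list alone. Car2, carbonic anhydrase 2, had a log2 difference of 6.11 (SE 1.59), with an adjusted p over the 4 tested list members of 0.0169 from limma and of 0.845 over all genes, but 2 Eμ-Myc values lay at background, so its fold is poorly determined. It read 3.14, 3.26, 6.79 and 7.20 in the Eμ-Myc arrays and 6.90, 10.87, 11.20, 12.01 and 15.05 in the double-transgenic ones. The globin genes Hba-a2 and Hbb-b2 had differences of 0.14 (SE 0.10) and 0.16 (SE 0.19), so the list's mean of 1.57 (exact permutation p = 0.0317, adjusted over the lists 0.667) came mainly from Car2. Both globin genes read near background, with Eμ-Myc and double-transgenic means of 4.23 and 4.37 for Hba-a2 and 4.83 and 4.99 for Hbb-b2. Their small differences therefore say little about erythroid cells. Pkm was the single gene that passed over the glycolysis and hypoxia list alone (limma adjusted p = 0.00771), in a list with 8 higher and 9 lower genes and a mean of 0.05, where Bnip3 had 1.05 (SE 0.42) and Ero1a -0.37 (SE 0.11). In total, 2 genes passed over their own list alone and 0 over all genes. The adjustment was made within each of the 30 lists and not across them, so a few such calls can arise with no effect. The remaining lists did not pass camera: mean log2 differences were 0.10 for the TTP family, 0.23 for ARF-p53 and RB regulators, 0.11 for the BCL2 family, -0.03 for the immediate-early response, 0.09 for the interferon response, 0.14 for the unfolded protein response, -0.15 for the heat shock response and -0.03 for oxidative phosphorylation. Among cell type markers they were -0.03 for mature B cells, -6.07e-04 for pan-B genes, 0.01 for germinal centre B cells, -0.17 for plasma cells, 0.44 for T cells, 0.62 for natural killer cells, -0.09 for dendritic cells and -0.16 for stroma and endothelium, and -0.80 over the 2 megakaryocyte genes, too few to be tested. Mean and median differed in sign for the TTP family (median -0.02), glycolysis (-5.05e-03), heat shock (0.04), pan-B (0.11), germinal centre B cell (-0.08) and stromal genes (0.06). Camera pointed to lower genes against a positive mean for the BCL2 family, interferon, glycolysis, unfolded protein and T cell lists, and to higher genes against a negative mean for pan-B genes. Xist exceeded 10 on the log2 scale in 2 of 4 Eμ-Myc and 2 of 5 double-transgenic arrays, so both groups hold animals of both Xist states, and the sex-linked list, left out of the count, had a mean of 0.14.

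Some lymphomas stood apart from others in the median level of a chromosome's genes. Each value is a chromosome's median log2 deviation from each gene's median over the 9 arrays, and 13 of 180 pairs of a chromosome and an array deviated by 0.15 or more, a limit chosen after the medians were seen. Of the 13, 10 were up and 3 down, in 4 of 4 Eμ-Myc and 3 of 5 double-transgenic arrays. Chromosome 16 stood 0.50 higher in Eμ-Myc replicate 4 over 342 genes, chromosome 19 stood at -0.46 in double-transgenic replicate 3 and 0.33 in replicate 5, and chromosome 17 was 0.33 higher in replicate 5. Chromosome 12 was 0.36, chromosome 18 was 0.34 and chromosome 14 was 0.20 higher in Eμ-Myc replicate 3, and chromosome 15 was 0.21 higher in double-transgenic replicate 3. Chromosome 3 was higher in Eμ-Myc replicate 1 (0.27) and double-transgenic replicates 1 (0.26) and 5 (0.26), and lower in Eμ-Myc replicates 2 (-0.18) and 3 (-0.19). The arrays with higher values also raise the median that serves as reference, so the lower values may come in part from it. The whole-chromosome medians of the other 167 pairs lay between -0.08 and 0.13. Such a median can miss a shift of a part of a chromosome. In Eμ-Myc replicate 1 the last of 4 equal parts of chromosome 16, in gene order, had a median of 1.24, against 0.0127 over the whole chromosome. No test across groups was made of these values.

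**Figure D4:**
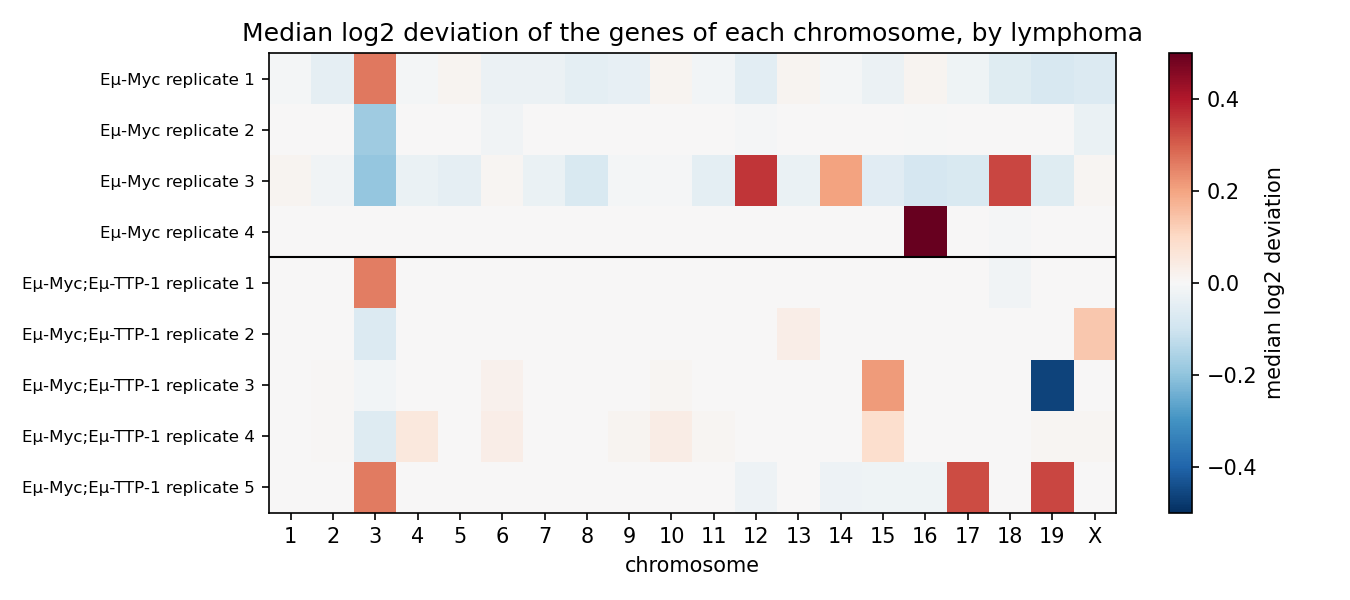
Median log2 deviation of the genes of each chromosome (columns) in each lymphoma (lines), relative to each gene's median over the 9 arrays. Colour gives the deviation from -0.5 to 0.5; single arrays stand apart, such as chromosome 16 in Eμ-Myc replicate 4 at 0.50.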

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

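The test of a wrong label for Eμ-Myc replicate 3 was written after its Slc25a13 value and the fit without it had been seen, and the 0.15 limit for chromosome shifts was chosen after the medians had been seen. Single samples stood far from the rest of their group in 18 of 200 groups of values tested, where chance gives about 1 in 20, or 10.

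Ccnd1 was low in Eμ-Myc replicate 1 (8.86 against 12.22 to 12.83) and in double-transgenic replicate 2 (8.03 against 12.60 to 12.82). In Eμ-Myc arrays, Synj2 read 2.29 in replicate 1 (others 3.03 to 3.14), Slc25a13 8.24 in replicate 3 (others 1.91 to 2.23), Cecr2 4.41 in replicate 3 (others 9.56 to 10.49), Tspan33 6.85 in replicate 3 (others 4.11 to 4.32) and Adgre1 9.97 in replicate 4 (others 8.02 to 8.28). In double-transgenic replicate 2, Wfdc21 read 7.48 (others 6.26 to 6.54), Ero1a 9.999 (others 9.78 to 9.83), Prtn3 10.60 (others 2.91 to 4.38) and Hbb-b2 5.65 (others 4.81 to 4.86). Rnd2 read 3.99 in double-transgenic replicate 1 (others 3.77 to 3.82) and Bcl3 5.24 in replicate 4 (others 6.67 to 7.12). Of the list means, p53-activated genes read 8.56 (others 8.74 to 8.76) and the unfolded protein response 11.47 (others 11.58 to 11.60) in Eμ-Myc replicate 1, precursor B cell genes 6.79 in Eμ-Myc replicate 2 (others 9.14 to 9.47), and mature B cell genes 8.86 in Eμ-Myc replicate 4 (others 9.53 to 9.62) and 7.66 in double-transgenic replicate 2 (others 9.44 to 10.15).

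For the gene lists and for genes at an unadjusted p under 0.05, chance could not be excluded by 100 splits of the arrays. At least the real 7 gene lists came from 28 of the 100 splits, the real one included. Among the other splits the highest count was 9 and the median 5, and 98 gave at least 1 list. At least the real 577 genes at an unadjusted p under 0.05 came from 21 of the 100 splits, the real one included, with 1281 the highest other. The count of genes past limma's adjusted threshold decides nothing here, since all 100 splits must give at least the real 0. Of the other splits, 7 gave any gene and the highest gave 36. The splits tested no other structure of the samples, and fits with Xist or the replicate numbers are given below.

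The shifts of chromosome medians in some lymphomas may reflect a change of the whole chromosome. All 13 shifted pairs had the sign of the shift, and at least 1/3 of its size, in each of 4 equal parts in gene order. These pairs were chosen by the median of the whole chromosome, so changes of a part were left out beforehand. Chromosome 16 of Eμ-Myc replicate 1, at 1.24 in its last part and 0.0127 as a whole, was not among them. A few strongly changed genes cannot move a median over 247 to 520 genes. Choosing pairs by their medians thus left that explanation out in advance, and the values are no separate evidence against it. The test set before the shares were seen asked for at least 65% of the genes on the side of the shift in every pair. Chromosome 3 of Eμ-Myc replicate 3 had 63.6%, so that bound was not met in every pair. The other 12 pairs had 67.9% to 89.1%. DNA copy number was not measured, and no biological explanation was tested.

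Eμ-Myc replicate 3 lay near the double-transgenic group: over the 100 genes with the smallest p without this array, its median position was 0.972, where 0 is the Eμ-Myc and 1 the double-transgenic mean. A wrong label stays open and cannot be told apart from chance, because the other Eμ-Myc arrays, left out the same way, also lay on the double-transgenic side at 0.739, 0.581 and 0.719, and with no effect the expected position is 0.625 for an Eμ-Myc array. The double-transgenic arrays lay at 0.563 to 0.737, where 0.5 is expected with no effect. On the second principal component this array stood at -38.9, beside the double-transgenic arrays (-2.43 to -32.9) and apart from the other Eμ-Myc arrays (28.7 to 57.5). Without replicate 3, 8 genes passed limma's threshold and 0 gene lists passed camera.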

How the results depend on the processing

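Centring by chromosome was chosen after seeing the data. The cause of a moved value was not tested.

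The count of genes past limma's threshold stayed at 0 when no array was left out in turn, with 532 to 1283 genes or probe sets at an unadjusted p under 0.05. Leaving out each array gave 0 to 8 genes: 8 without Eμ-Myc replicate 3 (Slc25a13, Acy3, Capn5, Dpy19l3, Gm2629, Prelid2, Rubcn and Zc2hc1a, named after their values were seen; Slc25a13 had a limma adjusted p of 4.81e-06, over a range up to 0.981 in the other alternatives) and 1 without Eμ-Myc replicate 4 (Mucl2), with 454 to 794 genes at an unadjusted p under 0.05. The 7 lists past camera's threshold became 3 without a filter, 4 after median centring and 1 with array weights, and 0 with an estimated correlation, 0 with fry and 0 with the permutation of list means. Leaving out each array gave 0 to 7 lists: 0 without Eμ-Myc replicate 3, 3 without double-transgenic replicate 2 and 4 without Eμ-Myc replicate 1, when the cell cycle lists were lost. Of 1513 alternative values of the 70 named genes other than Zfp36, 1465 kept their direction and side of the threshold, 47 changed sign and 1, of Slc25a13, passed the threshold. Of 695 alternative values of the 28 lists, 574 kept both, 52 changed sign, 67 lost a camera call and 2 gained one. Of 25 alternatives each, the call was lost in 18 for macrophages, 12 for precursor B cells, 10 for NF-kB, 10 for class II, 6 for S phase and 6 for mitosis and 5 for granulocytes. The immediate-early list gained a call for lower genes without Eμ-Myc replicate 1 (mean -0.22, camera adjusted p = 0.0401) and without double-transgenic replicate 5 (mean -0.16, 0.0291). Intensities near 16 and below carry little signal over background.

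Without a filter on low values, the log2 difference changed sign to -0.13 for germinal centre B cell and -0.0924 for natural killer and cytotoxic cell. With a log2 filter of 6, the log2 difference changed sign to 0.0471 for immediate-early response. With all probe sets, the log2 difference changed sign to -0.0203 for MYC-activated genes, -0.047 for BCL2 family, 0.0458 for immediate-early response, 0.0464 for pan-B lineage, -0.13 for germinal centre B cell and 0.00507 for plasma cell. With the mean of the probe sets of a gene, the log2 difference changed sign to -0.0138 for Bub1b, -0.0202 for TTP family, 0.0813 for immediate-early response, 0.0155 for pan-B lineage and -0.10 for germinal centre B cell. Without _x_at probe sets, the log2 difference changed sign to 0.57 for Vps52. After quantile normalization, the log2 difference changed sign to -0.0591 for germinal centre B cell. After median centring, the log2 difference changed sign to -0.0555 for Bub1b, -0.0021 for H2-DMb2, -0.0505 for MYC-activated genes, -0.0302 for glycolysis and hypoxia response and -0.0624 for germinal centre B cell. With array weights, the log2 difference changed sign to 0.15 for Zfp36, -0.0576 for Bub1b, -0.39 for interferon response, 0.28 for mature B cell, 0.12 for pan-B lineage, -0.0568 for germinal centre B cell and 0.0223 for dendritic cell. With a pseudocount of 16, the log2 difference changed sign to 0.33 for Prtn3 and 0.00649 for pan-B lineage. With the Xist covariate, the log2 difference changed sign to 0.28 for Prtn3 and 0.0143 for immediate-early response. After centring by chromosome, the log2 difference changed sign to -0.00406 for Bub1b and -0.0225 for H2-DMb2.

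When arrays were left out in turn, the range of the log2 difference crossed 0: -0.18 to 0.29 for Bub1b, -0.71 to 1.11 for Ccnd1, -2.09 to 0.0287 for Cecr2, -0.73 to 0.0763 for Chaf1b, -0.36 to 0.53 for H2-DMb2, -0.0028 to 0.21 for Hbb-b2, -0.51 to 1.22 for Ltb, -1.79 to 0.54 for Mmp9, -0.00302 to 0.20 for Myc, -1.48 to 0.51 for Prtn3, -0.39 to 0.53 for Tspan33, -0.33 to 0.34 for Ube2c, -0.14 to 0.12 for Zfp36, -0.30 to 0.0254 for Zfp36l1, -0.0448 to 0.0865 for MYC-activated genes, -0.0249 to 0.30 for TTP family, -0.73 to 0.42 for dendritic cell, -0.23 to 0.15 for germinal centre B cell, -0.22 to 0.15 for immediate-early response, -0.35 to 0.70 for interferon response, -0.22 to 0.40 for mature B cell, -0.15 to 0.21 for pan-B lineage, -0.46 to 0.16 for plasma cell and -0.33 to 0.11 for stroma and endothelium. It kept its sign but moved by a factor over 1.5 from the full value: -2.42 to -0.97 for Adgre1, -1.12 to -0.30 for Bcl3, -1.09 to -0.18 for Birc3, 0.63 to 1.26 for Bnip3, -0.98 to -0.39 for Ccne1, -1.63 to -0.83 for Cd74, 0.16 to 0.38 for Cdk4, 0.0385 to 0.46 for Cflar, 0.71 to 1.27 for Gins2, 0.35 to 1.43 for H2-Ob, -1.01 to -0.26 for antigen presentation class II, 0.0719 to 0.41 for ARF-p53 and RB pathway regulators, 0.0125 to 0.24 for BCL2 family, 0.12 to 0.53 for cell cycle mitosis, 0.09 to 0.48 for cell cycle S phase, 0.00754 to 0.0929 for glycolysis and hypoxia response, -0.30 to -0.0223 for heat shock response, 0.0281 to 0.33 for known TTP target mRNAs, -0.55 to -0.17 for macrophage and monocyte, 0.0534 to 1.17 for natural killer and cytotoxic cell, -2.98 to -1.21 for neutrophil and granulocyte, -0.51 to -0.095 for NF-kB response, -0.0913 to -0.00254 for oxidative phosphorylation, 0.71 to 1.60 for progenitor and precursor B cell, 0.28 to 0.77 for T cell, 0.0708 to 0.19 for unfolded protein response, 0.13 to 0.58 for Lyz1, 0.22 to 0.85 for Lyz2, -1.02 to -0.37 for Ndrg1, -0.32 to -0.12 for Odc1 and 1.66 to 3.60 for Rag2.

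With the replicate numbers as a block, over the 8 arrays that share numbers, limma called 0 genes and camera 6 lists, and Zfp36 had -0.0786. The block leaves out double-transgenic replicate 5, and the differences equal those of the fit without that array and without a block, where camera called 7 lists, so the missing array and not the block moved them. The sign changed to -0.031 for Ccnd1, -0.0798 for Bub1b, -0.13 for Ltb, -0.25 for H2-DMb2, 0.44 for Prtn3 and -0.11 for germinal centre B cell. The labels do not say whether the numbers pair the samples, and pairing was not tested. Deviations of same-numbered arrays from their group means correlated weakly, at -0.09, 0.09, -3.34e-03 and 0.20, and 2 of 4 numbers correlated best with their own.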

Other observations

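The clock test was written after the value of Arntl had been seen, and before those of the other clock genes were.

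Arntl was higher in all 5 double-transgenic arrays than in all 4 Eμ-Myc arrays, a log2 difference of 2.49 that did not pass limma's adjusted threshold. Another time of day at collection may be the cause, and then clock genes of the opposite phase would be lower. The 7 tested genes of that phase had a mean log2 difference of 0.224, with 2 lower and 5 higher (exact permutation p = 0.262, two-sided), among them Per3 at 0.81, Dbp at 0.53 and Per1 at -0.46. The mean lay on the side that speaks against the time of day but within its spread, and collection times are not given in the labels, so this stays open. The 2 tested genes of Arntl's own phase, Clock and Cry1, were at -0.61 and -0.998.

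In a principal component analysis of the tested genes, the first component held 27.4%, the second 19.6% and the third 17.2% of the variance, with exact permutation p of 0.968, 0.0952 and 0.302 between the genotypes (two-sided). The second component read 57.5, 35.6 and 28.7 in Eμ-Myc replicates 1, 2 and 4, -38.9 in Eμ-Myc replicate 3 and -2.43 to -32.9 in the double-transgenic arrays, so all arrays but replicate 3 divided by genotype. The SD within a group was larger in Eμ-Myc for 59.4% of genes, with medians of 0.361 in Eμ-Myc and 0.297 in double-transgenic lymphomas; the difference was not tested.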
